A study of Rattus norvegicus with 6 samples.

How the data were processed

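Amniotic fluid was collected from control and preeclampsia-model rats on embryonic day 18.5, and the cells were cultured and sequenced at passage 4, per the labels. The labels' protocols describe RNA enriched on oligo(dT) beads, fragmented, copied with random primers and ligated to adapters carrying unique molecular identifiers. Whether reads were collapsed by identifier is not given in the sources used here. The submitters' processing notes name cutadapt 1.9, FastQC, HISAT2 2.2.1 and StringTie 2.1.6, without roles or settings. The genome build is not given in the sources used here, and the sequence names in the table are those of the mRatBN7.2 chromosomes; coordinates are printed as the table gives them.

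The authors deposited 1 table with a whole-number count and an FPKM value (fragments per kilobase of transcript, scaled to library size) per gene and library, per the file headers. Deposited FPKM equalled the count scaled by 1 factor per gene and 1 per library, the largest deviation being 0.022 on the log2 scale over 2894 genes with FPKM over 20 in all libraries. Among counts from 1 to 15, between 35.1% and 38.0% per library were multiples of 4, against 20% if evenly spread. The deposited counts may therefore have been computed from coverage, not from single reads, and low counts are less certain than their size implies. Gene symbols were those of the table, and 2325 tested genes with only a locus identifier were treated as having no symbol and were counted but not named.

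Libraries were grouped by the labels, 3 per group, and no 2 libraries were duplicates, the smallest chi-square per degree of freedom between any pair being 140. The design had set limma on log2 FPKM as the main test, replaced by edgeR if counts were in the table; counts were, so edgeR is the main test. Genes were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with the group as the only term and Benjamini-Hochberg adjustment over 15776 genes. A gene was called at an adjusted p under 0.05, by edgeR where no tool is named. The biological coefficient of variation was 0.418 and the median standard error of a log2 fold change 0.263, so the spread between libraries, and not the depth of 48402185 to 59193961 counts, set the precision. Fold changes are preeclampsia over control, and values in the text are the mean ± SD of FPKM.

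There were 44 gene lists, written before the data were examined, of which 41 had at least 5 tested members. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, with adjustment over the lists. Camera with an estimated correlation and fry were alternatives. Fry called 0 lists for movement in one direction and 12 for movement in either. GO and KEGG terms of the table with 15 to 300 tested members were tested with camera against the annotated genes, 14626 for GO and 6874 for KEGG. List means per library were compared by an exact permutation test, which cannot go below 0.1 with 3 against 3.

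The genes to be named were set beforehand: those called, or, where none was called in a direction, the 5 with a symbol and the smallest p there; for each list described, 2 to 4 members with the highest mean FPKM, of those used here, where none was called; and Nt5e, Thy1, Eng, Cd44, Ptprc, Cd34, Flt1, Vegfa and Pgf. Members called adjusted over a list alone were named after their values were seen.

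Alternatives were DESeq2 1.42.0, no filter, the replicate number as a block, each library left out, and limma on log2(FPKM + pseudocount) with pseudocounts of 1, 0.5 and 0.1, other filters, scalings and weights. With limma, genes with a mean FPKM of at least 1 were tested, and fold changes on that scale understate the change of low genes. With a library left out in edgeR, genes were filtered anew, so a list's tested members could change. Scripts were tested on simulated data. In counts drawn for the comparison of preeclampsia with control at the measured spread, with 15339 genes tested, edgeR recovered 2, 27, 29 and 39 of 50 genes changed by 2, 4, 8 and 16 fold, with 1 unchanged gene called. DESeq2 recovered 17, 38, 43 and 45, with 85 unchanged genes called.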

Results

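RNA was sequenced from cells grown out of rat amniotic fluid that had been collected on embryonic day 18.5, from control pregnancies and from a rat model of preeclampsia, a disorder of pregnancy with maternal hypertension. The cells, which the labels call mesenchymal stem cells, were harvested at passage 4. There were 3 control and 3 preeclampsia libraries. Total counts were 49598012, 51790772 and 51550576 in control libraries 1 to 3 and 51942454, 59193961 and 48402185 in preeclampsia libraries 1 to 3. The table listed 22085 genes, of which 605 had no count in any library, and 15776 were tested. The titles number the libraries as control pregnancy 1 to 3 and preeclampsia 1 to 3. Beyond that, how many animals or fetuses each library holds is not given in the sources used here, and every p-value of a single gene measures the spread between these libraries. Those of lists and terms by camera also rest on the correlation set among genes. The preset 0.01 treats members as nearly independent, while the estimate for the ribosomal protein list was 0.33. For the immediate early genes the estimate was 0.013, near the preset, and their call was lost all the same. A call lost with an estimated correlation thus need not be due to correlation among genes.

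The first question was which cell types the cultures resembled. The mesenchymal genes Cxcl12, Vim and Thy1 stood far above the blood cell genes Ptprc and Cd34 in both groups, while macrophage genes such as Laptm5 were measured too. Thy1, a surface glycoprotein of stromal cells, stood at 368 ± 93.8 FPKM in the control group and 369 ± 117 in the preeclampsia group (SD, n = 3 each). The chemokine gene Cxcl12 reached 1636 ± 409 and 1805 ± 439 FPKM, and the intermediate filament gene Vim reached 437 ± 20.9 and 479 ± 123 FPKM. Cd44, a hyaluronan receptor, was at 334 ± 152 and 193 ± 116 FPKM. Nt5e, which encodes the ectonucleotidase CD73, was at 23.0 ± 19.2 and 58.1 ± 46.1 FPKM, and Eng, a TGF-beta co-receptor, at 19.9 ± 21.5 and 15.9 ± 17.6 FPKM. The leukocyte gene Ptprc was at 0.613 ± 0.375 and 0.820 ± 0.702 FPKM. The macrophage gene Laptm5, at 38.4 ± 25.4 and 64.7 ± 56.7 FPKM, had a mean above those of Nt5e and Eng in both groups. Lyz2, of the same list, was at 21.7 ± 17.1 and 26.2 ± 29.3 FPKM. Cd34, a marker of blood progenitors and endothelium, was at 0.760 ± 1.32 and 0.163 ± 0.182 FPKM and was listed at 0 in 2 control libraries and 1 preeclampsia library. None of these identity genes was called between the groups by edgeR's quasi-likelihood test, the adjusted p running from 0.708 for Cd44 to 0.991 for Thy1.

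The libraries differed among themselves in ways that the groups did not explain. The first principal component, with 33.3% of the variance, set preeclampsia libraries 2 and 3 apart from the other 4, and the second, with 22.7%, set control library 3 apart. Preeclampsia library 1 lay at -40.92 on the first component, between the control libraries at -44.36 and -34.46. Preeclampsia libraries 2 and 3 were the most alike of all pairs, with a correlation of 0.963 across genes. Genes of the G2 and M phases averaged 6.41 log2 CPM in preeclampsia library 1 and between 4.25 and 5.40 in the other 5. Markers of macrophages and other blood cells, such as Cd163 and Laptm5, averaged -0.08 and 0.80 log2 CPM in control library 3 and preeclampsia library 1, and from 2.67 to 4.38 in the other 4. The Y-linked gene Eif2s3y varied within both groups, at 16.9, 1.85 and 59.7 FPKM in control libraries 1 to 3 and at 5.02, 25.4 and 30.6 FPKM in preeclampsia libraries 1 to 3.

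**Figure D1:**
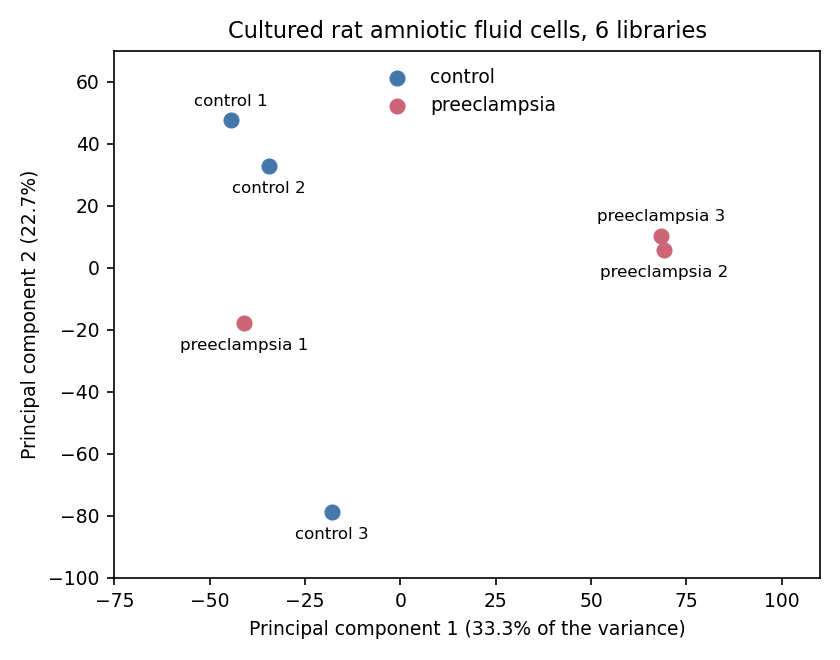
Principal components 1 and 2 of the log2 CPM of the 15776 tested genes, 1 point per library, coloured by group. Preeclampsia libraries 2 and 3 lie at 69.2 and 68.5 on the first component, and control library 3 lies at -78.65 on the second.

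The main comparison asked which genes differed between cells from the preeclampsia model and cells from control pregnancies. Msln, which encodes the surface protein mesothelin of mesothelial cells, stood at 1.62 ± 0.501 FPKM in the control group and 16.6 ± 4.56 in the preeclampsia group, a log2 fold change of 3.38 (SE 0.31). Ccn2, the connective tissue growth factor gene and a target of TGF-beta and YAP, stood at 2092 ± 239 and 665 ± 120 FPKM, a log2 fold change of -1.63 (SE 0.20). Crmp1, a cytoskeletal gene of neurons, stood at 4.77 ± 1.15 and 0.190 ± 0.104 FPKM (-4.62, SE 0.52). In each of these genes the 3 libraries of one group did not overlap the 3 of the other. No gene passed an adjusted p of 0.05 in edgeR's test, the smallest adjusted p being 0.228, while 1450 had an unadjusted p under 0.05 and DESeq2 called 302.

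The other genes with the smallest p in the higher direction, none of them called, were Ripor3, Lvrn, Col16a1 and Nfil3. Ripor3 was at 4.28 ± 1.14 and 21.5 ± 1.52 FPKM in the control and preeclampsia groups, with a log2 fold change of 2.35 (SE 0.24). Lvrn, an aminopeptidase gene, was at 1.47 ± 0.574 and 20.2 ± 11.2 FPKM (3.76, SE 0.53). Col16a1, a fibril-associated collagen gene, was at 20.8 ± 0.815 and 44.8 ± 2.55 FPKM (1.13, SE 0.12). Nfil3, which encodes a basic leucine zipper repressor, was at 4.82 ± 0.415 and 9.21 ± 0.544 FPKM (0.96, SE 0.13). Those in the lower direction, likewise not called, were Aff3, Dcdc2 and Vsnl1. Aff3, a nuclear factor gene, was at 22.9 ± 2.80 and 6.23 ± 1.49 FPKM (-1.87, SE 0.21). Dcdc2, a doublecortin-domain gene, was at 1.56 ± 0.288 and 0.207 ± 0.071 FPKM (-2.93, SE 0.34), and Vsnl1, a neuronal calcium sensor gene, at 3.27 ± 1.50 and 0.337 ± 0.060 FPKM (-3.24, SE 0.38). The adjusted p of these 10 genes, Msln, Ccn2 and Crmp1 included, lay between 0.228 and 0.313. In the table's coordinates, Msln spans 14771946 to 14781382 on chromosome 10, Ccn2 20802199 to 20805315 on chromosome 1, Crmp1 73509933 to 73556177 on chromosome 14 and Col16a1 142388376 to 142442825 on chromosome 5.

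**Figure D2:**
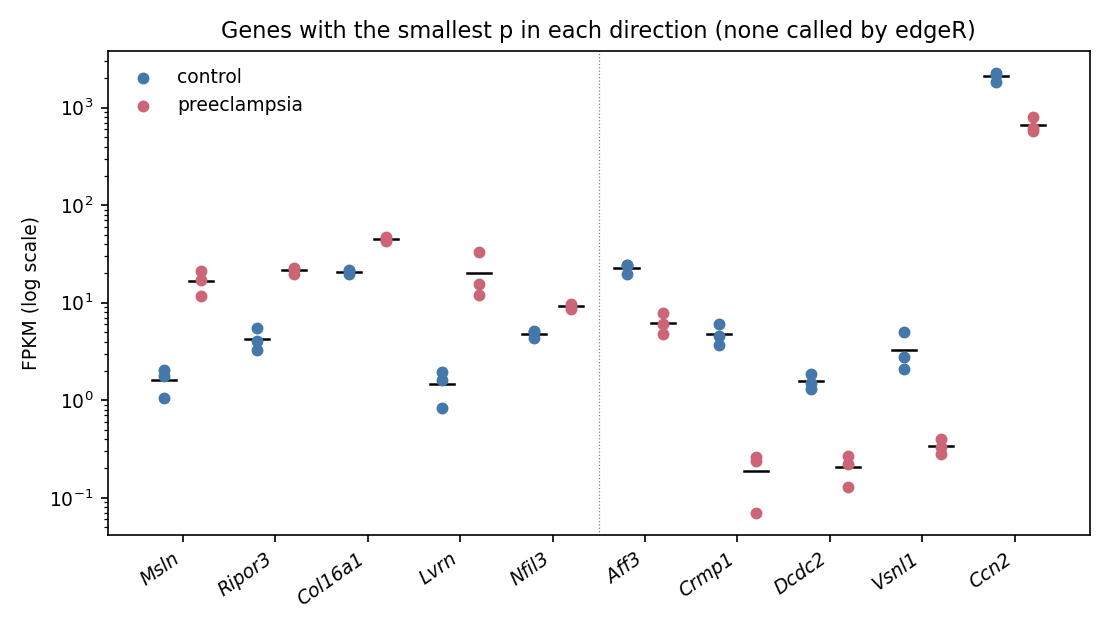
FPKM on a log axis of the 5 genes with the smallest p in each direction, 1 point per library, with black bars at the group means. The 3 control and 3 preeclampsia libraries do not overlap in any of the 10 genes, as for Msln at 1.06 to 2.03 against 11.8 to 20.9 FPKM.

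Across all tested genes, 1450 had an unadjusted p under 0.05 in edgeR, 651 higher and 799 lower in the preeclampsia group, where 788.8 would be expected by chance. In 2454 genes (15.6%) the groups did not overlap, against 10% by chance. DESeq2, run on the same counts, called 302 genes, 128 higher and 174 lower, including all 10 named above. The DESeq2 count is not the main result, since the design had set edgeR as the main test for counts. In simulated counts with the spread measured here, DESeq2 also called 85 unchanged genes and edgeR 1. Genes were drawn independently there, so the simulation leaves out structure shared between genes across the libraries. Without control library 3 edgeR called Tgfbr3 (log2 fold change 2.94), and without preeclampsia library 1 it called Enpp3 (2.18) and Pitx1 (-7.22), named here only because they were called.

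Among the 41 fixed gene lists tested, 6 rose in the preeclampsia group by camera with the preset correlation, led by the cytosolic ribosomal proteins. All 66 tested members of that list were higher, with a median log2 fold change of 0.38 and an adjusted p of 4.5e-30, against an adjusted p = 0.646 with an estimated correlation. Over all genes edgeR called none of them and DESeq2 called 2, Rpl12 and Rpl5, and 17 were called by edgeR adjusted over the list alone. All 17 lay just under the threshold, at an adjusted p of 0.0487 to 0.0491, so this count would change with a slight shift. Rplp0, a protein of the ribosomal stalk, was at 2407 ± 283 and 2934 ± 157 FPKM (0.31, SE 0.13), Rpsa at 1156 ± 88.5 and 1413 ± 106 (0.31, SE 0.13) and Rpl6 at 687 ± 45.1 and 920 ± 33.3 (0.44, SE 0.12). These genes have processed pseudogenes, so their counts may include reads that belong to copies. The estimated correlation gave the highest adjusted p of the list's alternatives, 0.646, the lowest being 6.8e-32. The list's mean per library gave the smallest p that an exact two-sided permutation test can reach with 3 against 3, 0.1 (0.51 adjusted over the lists).

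Genes of the hypoxia response and of glycolysis rose as lists. In the hypoxia list 26 of 31 genes were higher, with a median of 0.59 and an adjusted p of 5.1e-06, against an adjusted p = 0.733 with an estimated correlation. Stc1, a secreted glycoprotein gene, was at 114 ± 52.2 and 348 ± 180 FPKM (1.65, SE 0.51), P4ha1, a collagen prolyl hydroxylase gene, at 211 ± 56.5 and 242 ± 5.21 (0.22, SE 0.21), and the collagen cross-linking gene Lox at 463 ± 58.4 and 406 ± 91.6 (-0.17, SE 0.21). In the glycolysis list 17 of 21 were higher, with a median of 0.54 and an adjusted p of 1.2e-05, against an adjusted p = 0.733 with an estimated correlation. Ldha, encoding lactate dehydrogenase A, was at 5735 ± 2334 and 7450 ± 1287 FPKM (0.41, SE 0.29), Eno1 at 654 ± 38.7 and 758 ± 127 (0.23, SE 0.16) and Gapdh at 551 ± 171 and 832 ± 381 (0.62, SE 0.42). No member of either list was called by edgeR, over all genes or adjusted over the list alone, while DESeq2 called 2 hypoxia genes, Stc1 and Adm, and 0 of glycolysis. The estimated correlation gave both lists the highest adjusted p of their alternatives, the lowest being 1.7e-10 and 4.9e-10. Control library 3, at 5.97 log2 CPM for the hypoxia list, lay above preeclampsia library 1 at 5.80, and without it the mean log2 fold change of that list was 0.85 in place of 0.48.

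Genes of the extracellular matrix, of cholesterol synthesis and of oxidative phosphorylation rose by the same test, each list losing its call when a named library was left out. In the matrix list 22 of 35 genes were higher (median 0.28, adjusted p = 0.0059), against an adjusted p = 0.733 with an estimated correlation. Col12a1 was at 1781 ± 522 and 4204 ± 1331 FPKM (1.26, SE 0.33) and Lamc1 at 3072 ± 571 and 3688 ± 345 (0.28, SE 0.20), while Thbs1 was at 8110 ± 920 and 7309 ± 685 (-0.13, SE 0.20). Adjusted over the list alone, edgeR called 1 of its members, Col16a1, and over all genes DESeq2 called 2, Col16a1 and Col12a1, and edgeR 0. In cholesterol synthesis 21 of 25 were higher (median 0.33, adjusted p = 0.0012), against an adjusted p = 0.804 with an estimated correlation. Fdps was at 109 ± 41.3 and 124 ± 5.55 FPKM (0.20, SE 0.31) and Cyp51 at 68.3 ± 29.5 and 73.0 ± 12.1 (0.10, SE 0.34). In oxidative phosphorylation 37 of 42 were higher (median 0.11, adjusted p = 0.015), against an adjusted p = 0.804 with an estimated correlation. Atp5f1b was at 422 ± 31.1 and 448 ± 47.6 FPKM (0.11, SE 0.12) and Atp5pb at 261 ± 33.8 and 274 ± 10.7 (0.09, SE 0.11). No member of the last 2 lists was called by edgeR, over all genes or adjusted over the list alone, or by DESeq2 over all genes. The estimated correlation gave the highest adjusted p of each list's alternatives, the lowest being 8.9e-04 for the matrix, 2.7e-11 for cholesterol synthesis and 3.9e-04 for oxidative phosphorylation. The matrix list lost its call without control library 3 (adjusted p = 0.075), cholesterol synthesis without control library 2 (adjusted p = 0.432), and oxidative phosphorylation without control library 1, control library 2 or preeclampsia library 2 (adjusted p = 0.206, 0.101 and 0.299). The mean log2 fold change of the matrix list was 0.31, and 0.21 without preeclampsia library 3. That of cholesterol synthesis was 0.29, with 0.60 and 0.093 without control libraries 1 and 2. That of oxidative phosphorylation was 0.11, with 0.068, 0.18 and 0.16 without control library 1, control library 3 and preeclampsia library 1.

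Contractile genes, early response genes and TGF-beta targets fell as lists. Of the smooth muscle and myofibroblast markers 16 of 18 were lower (median -0.62, adjusted p = 0.0048), against an adjusted p = 0.756 with an estimated correlation. Acta2, the smooth muscle actin gene, was at 680 ± 539 and 249 ± 62.1 FPKM (-1.46, SE 0.63), the tropomyosin genes Tpm1 at 1100 ± 359 and 640 ± 108 (-0.78, SE 0.27) and Tpm2 at 1082 ± 350 and 806 ± 231 (-0.42, SE 0.33) and Cald1 at 2313 ± 433 and 1903 ± 171 (-0.27, SE 0.20). Of the immediate early genes 17 of 22 were lower (median -0.40, adjusted p = 0.0012), against an adjusted p = 0.646 with an estimated correlation. That estimate was 0.013, close to the preset 0.01, yet the unadjusted camera p went from 1.4e-04 to 0.021. The lost call of this list is therefore not explained by correlation alone. Ier3 was at 192 ± 43.3 and 85.2 ± 11.7 FPKM (-1.15, SE 0.19), Junb at 72.7 ± 5.94 and 54.3 ± 4.18 (-0.40, SE 0.11) and Dusp1 at 72.3 ± 18.4 and 41.9 ± 8.21 (-0.78, SE 0.24). Of the TGF-beta targets 18 of 27 were lower (median -0.34, adjusted p = 0.0048), against an adjusted p = 0.733 with an estimated correlation. Ccn2 was among them, while Col1a1 was at 2482 ± 639 and 3239 ± 917 FPKM (0.41, SE 0.31) and Fn1 at 2235 ± 528 and 2204 ± 437 (-0.01, SE 0.27). Over all genes edgeR called no member of the 3 lists; adjusted over the list alone it called 1 early response gene (Ier3) and 2 TGF-beta targets (Ccn2 and Smad7). DESeq2 called these and 2 contractile genes, Actg2 and Myh11, over all genes. The estimated correlation gave the highest adjusted p of each list's alternatives, the lowest being 2.0e-09 for the contractile, 3.9e-04 for the early response and 0.0013 for the TGF-beta list. The contractile list lost its call without control library 1 (adjusted p = 0.135) and the TGF-beta list without preeclampsia library 1 (adjusted p = 0.069). Without control library 1 the mean log2 fold change of the contractile list was -0.49 in place of -0.92, and that of the TGF-beta list -0.17 in place of -0.27.

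The p53 targets, mitochondrially encoded genes and YAP targets also fell as lists. Of the p53 targets and cell cycle inhibitors 20 of 26 were lower (median -0.25, adjusted p = 0.0055), against an adjusted p = 0.646 with an estimated correlation. Mdm2, the ubiquitin ligase that acts on p53, was at 170 ± 58.3 and 96.1 ± 3.36 FPKM (-0.80, SE 0.22), Ccng1 at 324 ± 50.1 and 210 ± 38.2 (-0.60, SE 0.18) and Phlda3 at 107 ± 17.5 and 69.5 ± 8.34 (-0.60, SE 0.17). All 13 messenger RNAs encoded in the mitochondrial genome were lower (median -0.24, adjusted p = 0.0031), against an adjusted p = 0.733 with an estimated correlation. COX1 was at 4020 ± 387 and 3286 ± 9.14 FPKM (-0.27, SE 0.16), CYTB at 2181 ± 60.1 and 1918 ± 199 (-0.17, SE 0.14) and ND4 at 1626 ± 90.3 and 1335 ± 123 (-0.27, SE 0.13). Of the YAP and serum response targets 18 of 23 were lower (median -0.14, adjusted p = 0.018), against an adjusted p = 0.733 with an estimated correlation. The actin gene Actb was at 5288 ± 755 and 5556 ± 931 FPKM (0.09, SE 0.22), the myosin gene Myh9 at 3138 ± 598 and 2693 ± 274 (-0.20, SE 0.21) and Ccn1 at 1722 ± 213 and 1564 ± 114 (-0.12, SE 0.16). By edgeR only Ccn2, in the YAP list, was called adjusted over the list alone, and no member of the 3 lists over all genes. DESeq2 called Ccn2 and Fhl2 of the YAP list, Plk2 and Cdkn2b of the p53 list and 0 of the 13 mitochondrial messenger RNAs over all genes. The estimated correlation gave the highest adjusted p of each of these lists' alternatives, the lowest being 6.7e-05 for p53, 3.9e-04 for the mitochondrial and 0.0020 for the YAP list. The YAP list lost its call without control library 1 (adjusted p = 0.185) and without preeclampsia library 1 (adjusted p = 0.179), its mean log2 fold change being -0.26, and -0.15 without control library 1. The mean of the p53 list was -0.20, with -0.42 and -0.13 without control libraries 1 and 3, and -0.46, -0.43 and -0.45 without preeclampsia libraries 1, 2 and 3. The level of this list in the preeclampsia libraries differed little, at 5.08, 5.11 and 5.15 log2 CPM. Genes were filtered anew in each of these fits, so the shifts may not reflect the library left out.

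**Figure D3:**
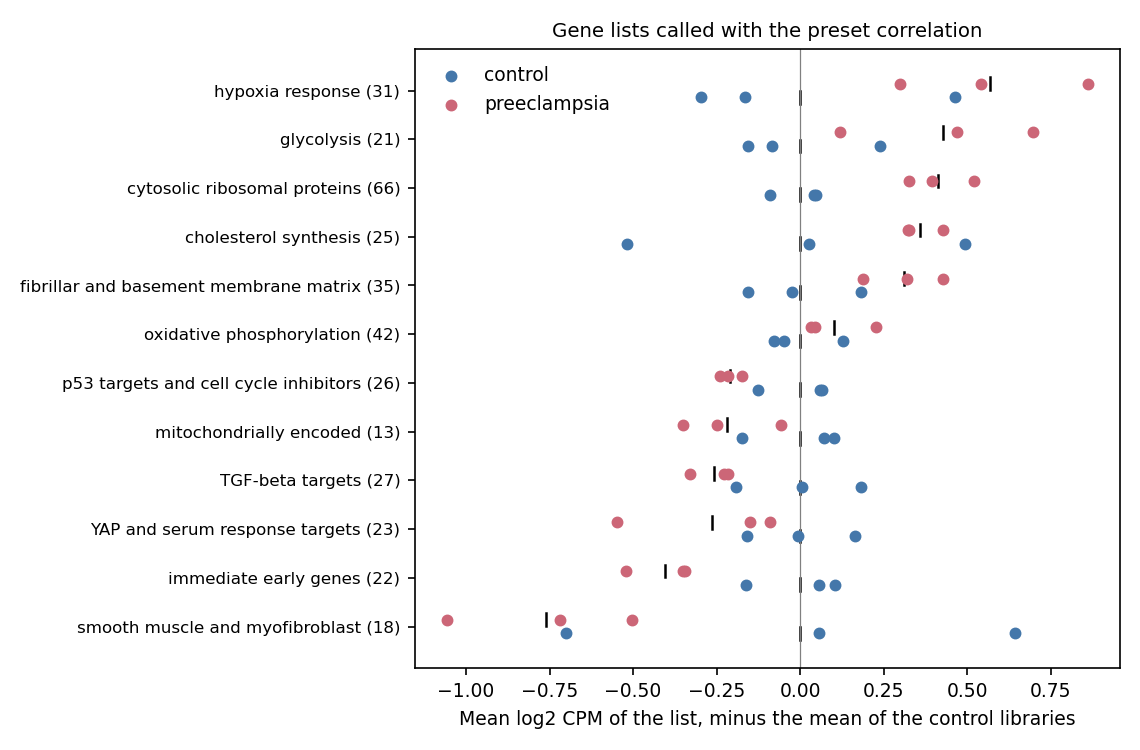
Mean log2 CPM per library of the 12 lists called with the preset correlation, minus the mean of the control libraries, with the number of tested genes in brackets and black bars at the group means. In the ribosomal protein list the preeclampsia libraries, at 7.18 to 7.37 log2 CPM, lie above the control libraries at 6.76 to 6.90.

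Of the angiogenic factors studied in preeclampsia, Vegfa, Flt1 and Pgf were not called (adjusted p = 0.797, 0.844 and 0.966). Vegfa was at 176 ± 20.6 FPKM in the control group and 216 ± 79.6 in the preeclampsia group (0.32, SE 0.28), and its log2 fold change was -0.048 without preeclampsia library 2. Flt1, which encodes a VEGF receptor and its soluble form, was at 1.69 ± 0.648 and 3.66 ± 5.49 FPKM, the latter resting on preeclampsia library 3 at 10.0, and its log2 fold change of 1.13 (SE 1.22) became -1.76 without that library. Pgf, encoding placental growth factor, was at 2.75 ± 4.09 and 2.15 ± 1.74 FPKM (-0.28, SE 1.34), and became 2.46 without control library 3, 0.18 without preeclampsia library 1 and 0.15 by limma on FPKM. Within the list of 33 angiogenic genes, 20 were lower and 13 higher, and the list was not called by camera (adjusted p = 0.601, from 0.108 to 0.936 over its alternatives). Fry's test for movement in either direction called it (adjusted p = 0.0064), as 1 of 12 lists that this test called. In edgeR 4 higher and 7 lower genes had an unadjusted p under 0.05. Over all genes 0 were called by edgeR and 8 by DESeq2, and 7 by edgeR adjusted over the list alone. These 7, chosen after their values were seen and all among the 8, were Ccn2, Fgf1, Fgf2, Tgfb2 and Tgfb3, all lower, and Angptl2 and Serpinf1, both higher. Tgfb2 was at 257 ± 121 and 72.3 ± 24.9 FPKM (-1.82, SE 0.45), and Serpinf1, which encodes an inhibitor of angiogenesis, at 205 ± 56.7 and 427 ± 82.2 (1.09, SE 0.24).

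Of the 41 lists tested, 29 were not called with the preset correlation. Mesenchymal stromal markers narrowly missed the threshold (median 0.13, adjusted p = 0.052), with 12 of 20 higher and 8 lower. Pdgfra, at 105 ± 10.1 and 291 ± 104 FPKM (1.50, SE 0.27), and Lum, at 72.2 ± 35.6 and 421 ± 185 (2.58, SE 0.51), were called adjusted over the list alone. Itgb1, at 973 ± 132 and 707 ± 103 (-0.45, SE 0.18), was lower and not called. The list passed the threshold under 12 of 19 alternatives (adjusted p from 0.0076 to 0.646). Epithelial markers missed it at the same adjusted p (5 of 8 lower), passing under 9 of 18 alternatives (0.0084 to 0.733). Krt7 was at 22.6 ± 10.2 and 39.2 ± 36.4 FPKM. The keratin genes Krt8, at 15.6 ± 19.2 and 0.990 ± 0.515 FPKM, and Krt18, at 7.34 ± 8.72 and 0.083 ± 0.104, and the desmosome gene Pkp1, at 32.5 ± 11.3 and 13.8 ± 4.68, were called adjusted over the list alone, all lower. Control library 2 held the highest Krt8 and Krt18, at 37.4 and 17.2 FPKM, against 1.12 and 0.480 in control library 1 and 8.41 and 4.38 in control library 3. Without control library 2 the mean log2 fold change of the epithelial list was -0.67 in place of -1.65, and without preeclampsia library 3 it was -3.43. Preeclampsia libraries 1 to 3 lay at 1.21, 1.47 and 1.07 log2 CPM for this list. Genes were filtered anew in each of these fits, so the shift to -3.43 may not reflect preeclampsia library 3. Blood cell and macrophage markers were higher in 18 of 19 genes (median 0.95, adjusted p = 0.052), with Laptm5 at 38.4 ± 25.4 and 64.7 ± 56.7 FPKM, the values following preeclampsia libraries 2 and 3 and not preeclampsia library 1. Genes of the G2 and M phases were higher in 35 of 36 (adjusted p = 0.659), with preeclampsia library 1 above every other library and the other two preeclampsia libraries within the control range. In the skeletal muscle, kidney, trophoblast, limb patterning and autophagy lists, none of them called, the median, the mean and the test differed in sign.

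Terms of translation led the functional terms that the table assigns to genes. Of 2405 terms tested by camera with the preset correlation, 26 were called, 17 higher and 9 lower in the preeclampsia group. The higher ones included the cytosolic large ribosomal subunit (135 genes, median 0.33, adjusted p = 3.9e-11), cytoplasmic translation (67 genes, median 0.28, adjusted p = 1.6e-06), the glycolytic process (42 genes, median 0.26, adjusted p = 0.020) and the MHC class I protein complex (18 genes, median 0.40, adjusted p = 0.018), a family of similar genes that may share reads. The lower ones included regulation of the actin cytoskeleton (230 genes, median -0.10, adjusted p = 0.028), potassium ion transmembrane transport (75 genes, median -0.29, adjusted p = 0.043) and ferric iron binding (18 genes, median -0.59, adjusted p = 0.043). No term was called with an estimated correlation, all named ones having an adjusted p = 0.996, and 62 had an unadjusted p under 0.05. Without control library 3 the count of called terms was 10, and without preeclampsia library 3 it was 46.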

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

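The settings that leave out both libraries lowest in Y-linked genes, add their level as a covariate or divide the counts by 4, and those for terms, were chosen after seeing the data. The count of called genes, 0 in edgeR, was 302 in DESeq2, 1 in limma with no filter (a gene with only a locus identifier, lower) and between 0 and 2 with each library left out, and 0 under every other setting run; with both libraries lowest in Y-linked genes left out it was also 0. The cause of the DESeq2 difference was tested only by simulation. The 1450 genes with an unadjusted p under 0.05 became 811 in limma with a mean FPKM of at least 5, where fewer genes were tested, and 991 to 2012 with each library left out. The 12 called lists became 0 with an estimated correlation and 0 by fry in one direction, 13 to 18 with each library left out, and 14 with both libraries lowest in Y-linked genes left out, 8 of them shared with the 12. None of the 12 turned direction under any setting run. By the exact permutation test of list means, the ribosomal, early response, TGF-beta, p53 and matrix lists gave p = 0.1. The hypoxia, glycolysis, contractile and mitochondrial lists gave 0.2, the YAP list 0.3, and the cholesterol synthesis and oxidative phosphorylation lists 0.4. The heat shock, mesenchymal and epithelial lists, which were not called, also gave 0.1. Adjusted over the lists, no p of this test was under 0.51. The 26 called terms became 0 with an estimated correlation and 10 to 46 with each library left out (10 without control library 3, 46 without preeclampsia library 3).

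The replicate numbers gave no clear pairing: same-numbered libraries had correlations of 0.048, 0.041 and 0.010 between their deviations from the group means. For control libraries 1 and 2 the same-numbered library was the best match, while control library 3 correlated more with preeclampsia library 2 (0.035). Correlations this small cannot tell whether the numbers mark a shared batch or litter. With the replicate block 0 genes, 15 lists and 18 terms were called, and 1196 genes had an unadjusted p under 0.05. The mesenchymal and epithelial lists passed the threshold under the block (adjusted p = 0.025 and 0.023).

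The 5 genes with the smallest p in each direction kept their direction under every setting in which they were tested, and passed the threshold in DESeq2 alone. They were chosen by p from these same libraries, so their constant direction and lack of overlap between groups are no independent support. Dcdc2 was tested in 13 of 23 settings and Crmp1 and Vsnl1 in 22. Genes that were not called turned sign as follows, and the cause was not tested. With each library left out, Thy1 ranged from -0.24 to 0.22, Eng from -1.76 to 1.10, Ptprc from -0.33 to 0.99, Cd34 from -3.45 to 7.28, Flt1 from -1.76 to 1.67, Vegfa from -0.048 to 0.52, Pgf from -1.06 to 2.46 and the mean of the angiogenic list from -0.35 to 0.19. With the replicate block in edgeR, Cd34 was 0.16, Flt1 -0.63, Pgf 0.76 and the mean of the angiogenic list 0.032, against -0.099 in the main fit. In limma on FPKM, Thy1 was -0.012 with pseudocounts of 1, 0.5 and 0.1, no filter, a mean FPKM of at least 5, no trend or the block, -0.0081 with quantile and -0.023 with TPM scaling and -0.070 with sample weights, but 0.018 with median-ratio scaling. In limma Pgf was 0.15 with a pseudocount of 1, no filter, no trend or the block, 0.58 and 0.29 with pseudocounts of 0.1 and 0.5, 0.24 with quantile, 0.19 with median-ratio and 0.31 with TPM scaling, and 0.82 with sample weights. Flt1 was -0.18 in limma with a pseudocount of 0.1.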

Other observations

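Among the tests below, those on dividing cells, on histone genes alone, on mitochondrial messenger RNAs and on mitochondrial transfer RNAs were chosen only after the result was seen. The following 8 genes were chosen singly after their values were seen and form no tested group. Over all genes edgeR called none of them and DESeq2 called all but Mmp2. Adjusted over the list alone, edgeR called Hes1 in the Notch list and Hand1 in the trophoblast list, but not Hand1 in the limb patterning list. Cthrc1, a secreted collagen-associated gene, was at 1.49 ± 1.11 FPKM in the control and 32.8 ± 20.8 in the preeclampsia group, and Ptn, the growth factor pleiotrophin, at 1.56 ± 0.476 and 13.5 ± 9.19. Sfrp1, a secreted inhibitor of Wnt signalling, was at 25.0 ± 17.8 and 187 ± 141 FPKM, and the gelatinase gene Mmp2 at 698 ± 28.8 and 1578 ± 670. In the other direction, Nefm, a neurofilament gene, was at 17.3 ± 14.3 and 0.697 ± 0.257 FPKM, Itga1, a collagen-binding integrin gene, at 61.2 ± 19.6 and 11.6 ± 4.11, and Hand1, a transcription factor gene of heart and extraembryonic tissue, at 2.99 ± 2.51 and 0.090 ± 0.070. Hes1, a target of Notch, was at 9.41 ± 1.83 and 3.34 ± 0.150 FPKM. The groups did not overlap in any of these 8 genes. The fixed lists that hold Mmp2 (matrix crosslinking and proteolysis), Sfrp1 (Wnt and BMP signalling), Hes1 (Notch signalling) and Hand1 (trophoblast, and limb patterning) were not called, with adjusted p = 0.549, 0.604, 0.629, 0.868 and 0.665 by limma's camera.

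The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. All 10 splits called 0 genes in edgeR, the highest other count being 0. The real split gave 1450 genes with an unadjusted p under 0.05 and 302 called by DESeq2; the highest other split, control libraries 1 and 2 with preeclampsia library 1 against the rest, gave 2214 and 865, so 2 splits, the real one included, gave as many in each measure. For lists the real split called 12 and the highest other 11, only the real split giving as many; for terms it called 26 and the highest other 191, with 7 splits giving as many, the real one included. That split, which also gave the 191 terms, parts the libraries by their order on the first principal component, and its DESeq2 and term counts, several times the real ones, point to a structure among the libraries, while its count of lists was 10. The ribosomal protein list was also called in 7 of the 9 other splits, with an adjusted p down to 2.7e-12 and a median up to 0.22, against 4.5e-30 and 0.38 in the real one. Every other split sets 2 libraries of one group with 1 of the other, so part of any group difference remains in it. Calls in these splits therefore do not show what would be called without a group difference.

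The higher level of all 66 genes of the ribosomal protein list in the preeclampsia libraries was weighed against technical explanations. These transcripts are short, but after each library's trend with transcript length was removed the median log2 difference was 0.39, against 0.38 before, and 896 genes matched on length and level had a median of -0.01. Under quantile, median-ratio and TPM scaling of FPKM the lowest median was 0.35, which argues against scaling. The test of more dividing cells could not decide, since preeclampsia libraries 2 and 3 lay within the control range. Their G2 and M phase genes, at 4.28 and 4.31 log2 CPM, lay below the control mean of 4.91. Their ribosomal means, 7.37 and 7.18, lay above every control library, at 6.76 to 6.90. In these 2 libraries the higher ribosomal level thus came without G2 and M phase genes above the control range. Control library 3 had similar G2 and M phase genes, at 4.25, with a ribosomal mean of 6.89. More dividing cells stays open, with preeclampsia library 1 at 6.41 for the G2 and M phase genes, of which 35 of 36 had a positive fold change. A difference between the preeclampsia model and control stays open as a hypothesis, as do a shared batch and the correlation among these genes, with which the list was not called.

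Both mitochondrial ribosomal RNAs were lower, mt-Rnr1 at 270 ± 21.8 and 136 ± 9.09 FPKM (-0.97, SE 0.12) and mt-Rnr2 at 101 ± 18.9 and 40.3 ± 8.75 (-1.30, SE 0.24), neither called by edgeR and both called by DESeq2. An equal fall of all mitochondrial transcripts is argued against, since the lowest of the 13 messenger RNAs was at -0.39, against -0.97 for mt-Rnr1. A smaller general fall with a further loss of ribosomal RNA stays open, since all 13 messenger RNAs were lower, with a median of -0.24. Weaker capture of RNA without a poly(A) tail on the oligo(dT) beads could lower them, while the 108 histone, snRNA and snoRNA genes, a set of which 1 histone gene had been seen before, had a median of -0.027 (SE 0.074), and the 82 small RNA genes among them 0.077. The 26 histone genes alone had a median of -0.56 (SE 0.19), with 23 lower, and all 20 tested mitochondrial transfer RNA genes were lower, with a median of -0.90 and 5 called by DESeq2. Weaker capture stays open, since 86.1% of the wider set and 69.2% of the histone genes lay under 1 CPM, as does a difference between the preeclampsia model and control, which was not tested separately.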
